A study of Mus musculus with 6 samples.

How the data were processed

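Liver RNA of male mice of the Balb/c and Balb/cBy substrains was measured on 6 one-colour Affymetrix arrays, 3 per substrain. Per the labels, the mice were housed in individual cages and received a diet with 58% of its energy as fat from an age of 8 weeks for 12 weeks, and livers were taken at 20 weeks. The labels call the arrays of a group biological replicates. Total RNA was extracted with Trizol, and biotinylated single-stranded cDNA was prepared from 500 ng of it, per the labels' protocols. The group of each array was taken from the strain given in its labels.

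The deposited values are log2 values per probe set, made by the authors with RMA (background correction, quantile normalization and a median-polish summary of the probes of a set) per the submitters' processing notes. The log2 scale was read from the values themselves. The version of RMA, the array annotation behind it, any filter and the genome build are not given in the sources used here. The table held 41345 probe sets in each of the 6 arrays, with no missing values and no column of per-sample values left unused. Array medians lay between 7.66 and 7.74. Pearson correlations between arrays over all probe sets lay between 0.972 and 0.988, and no array was identical to another. For arrays, depth has no counterpart in read counts, and it is the number of arrays that limits the precision.

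Gene names came from the platform annotation held by GEO, which can be old. It gave 1 gene symbol for 23521 probe sets and several for 1814, and 16010 were unnamed here. Only probe sets with 1 symbol were tested as genes. All symbols found by gene identifier in the reference table of mouse genes were current there. Where a gene had several probe sets (1082 genes), the probe set with the highest mean over all 6 arrays was used, which left 22180 genes. No filter on low values was applied. No coordinates are given, since no build is named.

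The comparison was Balb/cBy minus Balb/c. It was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on the log2 values, with no covariate and Benjamini-Hochberg adjustment over all genes, and a threshold of 0.05. Differences are given on the log2 scale with the moderated standard error (SE). Levels are means ± SD over the 3 arrays of a group. A fold is 2 to the power of the log2 difference. For gene lists, camera of limma was used with a preset inter-gene correlation of 0.01 and all tested genes as background, adjusted over the lists. Estimated correlations and fry (directional) were alternatives. An exact permutation test (two-sided) of 3 arrays against 3 cannot give a p below 0.1.

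The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The 31 lists had 534 entries, of which 474 were measured. They covered lipid, ketone, bile acid, sterol and glucose metabolism, oxidative phosphorylation, drug metabolism, sex-biased and Zhx2-regulated liver genes, stress responses, acute phase, interferon, MHC class I, circadian and cell cycle genes. Further lists held markers of macrophages, lymphocytes, neutrophils, stellate cells, cholangiocytes, endothelial cells, erythroid cells, adipocytes and exocrine pancreas. Named genes were Acads and Zhx2 always, and the 12 genes with the largest difference in each direction among those past the threshold whose groups did not overlap. Places left over were filled by genes with an unadjusted p under 0.01, no overlap and the largest difference, stated not to pass. Gene models without a proper symbol were counted and not named unless they led their direction. Of each list, up to 4 members past the threshold were named, or else the 2 with the smallest p as values, and up to 3 members past 0.05 when adjusted over the list alone. Hspa5, Asns and Atf4 were named beyond this rule, after their values were seen.

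The scripts were tested on simulated data, drawn for this comparison with the spread of the 22180 genes and 200 genes changed. The test recovered 30% of genes changed by 0.5 on the log2 scale, 96% of those changed by 1, and 100% of those changed by 2 or by 4, and it called 12 unchanged genes. A list shifted by 0.35 passed in 20 of 20 simulations, and in 14 of 20 with an estimated correlation. Unchanged lists passed in 7 of 600 tests. Genes were drawn independently of each other, while the estimated correlation within the real lists reached 0.596, for cholesterol synthesis and uptake. These simulated rates therefore do not hold for lists of correlated genes.

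The alternatives were the replicate number as a block, recentred arrays, a repeated quantile normalization, 2 filters on low values, the mean of all probe sets of a gene, all probe sets tested one by one, a trended and robust variance model, array weights, an ordinary test without moderation, other thresholds, and leaving out each array. Lists without Acads or without Ighm were added after the data were seen. Probe sets with several symbols or none were left out of the gene test, since they name no single gene, and were fitted apart from it. Scanner files and array batches were not used here.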

Results

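After 12 weeks of high-fat diet, genes of the unfolded protein response were higher in livers of Balb/cBy mice than of Balb/c mice, by a median of 0.34 on the log2 scale, led by Creld2, Sdf2l1 and Manf. Interferon response genes were higher by a median of 0.18, and target genes of the lipid-sensing receptor PPAR-alpha had a median difference of -0.19. These lists passed with a preset correlation between genes and none did with an estimated one, and of single genes 0 passed. With the preset correlation 13 lists passed for strain, and up to 16 for groupings of the arrays that mixed the strains. Acads had a log2 difference of -0.65 (SE 0.12) without overlap of the groups, and Obp2a, which differed most among the named genes, was higher by 3.99 in Balb/cBy, and by 4.69 without Balb/c replicate 3.

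The series holds 6 arrays of liver RNA, 3 from male Balb/c mice and 3 from male Balb/cBy mice, all 20 weeks old. Both groups received the same diet, in which fat made up 58% of the energy. Balb/c and Balb/cBy are substrains of a common albino inbred line that have been bred apart. Balb/cBy mice are known as carriers of a deletion in Acads, which encodes the short-chain acyl-CoA dehydrogenase of mitochondria. The comparison asks which liver transcripts differ between these substrains when both are fed fat. No group on another diet was analysed here, so the values say nothing of the response to the diet itself.

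Of 22180 genes tested with limma, 0 passed an adjusted p of 0.05, and 0 passed 0.1. The smallest adjusted p was 0.166, shared by 10 genes. An unadjusted p under 0.05 was reached by 833 genes, 575 higher and 258 lower in Balb/cBy, where 1109 would be reached by chance. The ordinary test without moderation called 0 genes as well, with 724 at an unadjusted p under 0.05. Values of the groups did not overlap for 1736 genes, or 7.83%, where chance gives 10%. The spread between mice of a group was wide next to most differences, with a median SE of 0.116 on the log2 scale. Weighting the arrays by their estimated quality gave 12 calls, among them Obp2a, Oas1g, Ighm, Creld2, Mid1, Manf and Macroh2a1. The weights were estimated from these same arrays and were lowest for Balb/cBy replicate 1 (0.467) and Balb/c replicate 3 (0.631). These calls therefore add no separate support. Of the 31 gene lists, 13 passed camera, 7 upward and 6 downward, while 0 passed with an estimated correlation and 0 with fry. Groupings of 3 arrays against 3 that mixed the strains gave 4 to 16 lists past the same threshold. The count of 13 is therefore no sign of strain. The exact permutation p of their list means was 0.1 for the unfolded protein response, interferon and neutrophil lists. It was 0.2 for the cell cycle and pancreas lists, and 0.3 for the PPAR-alpha, heat shock, ketone, beta-oxidation and stellate lists. For the macrophage and lymphocyte lists it was 0.7, and for acute phase genes 0.9. The count of lists was 8 without Balb/c replicate 3 and 8 without Balb/cBy replicate 1.

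Obp2a, an odorant-binding lipocalin, stood at 9.02 ± 1.23 in Balb/c and 13.0 ± 0.25 in Balb/cBy (SD, n = 3 each), a log2 difference of 3.99 (SE 0.51). Its 3 Balb/c arrays were spread widely, with replicate 3 at 10.4, and its adjusted p was 0.166. Without Balb/c replicate 3, Obp2a and Oas1g were the 2 genes that passed (by 4.69, adjusted p = 0.00037, and by 1.89, adjusted p = 0.0152). Oas1g, an oligoadenylate synthetase induced by interferon, was higher by 1.65 (SE 0.21). Immunoglobulin transcripts made up a further part of the genes that differed most. Ighm, the constant region of the mu heavy chain, was higher by 1.59 (SE 0.21), and the kappa variable segments Igkv4-72 and Igkv4-70 by 1.35 (SE 0.23) and 1.16 (SE 0.25). Jchain, which joins antibody chains, was higher by 1.12 (SE 0.28). Without Balb/cBy replicate 1, which had the lowest level of Ighm in its group, 3 genes passed, among them Ighm (by 1.86, adjusted p = 0.00943) and Igkv4-70 (by 1.49, adjusted p = 0.00947). For Obp2a, Oas1g, Ighm and Igkv4-70 the array left out was that of its group nearest to the other strain. Its removal widens the difference, so these calls add no support. Leaving out any other single array called 0 genes. Creld2, a chaperone-like protein of the endoplasmic reticulum, was higher by 1.22 (SE 0.15), and the interleukin-1 receptor Il1r1 by 1.19 (SE 0.16). The ubiquitin ligase Mid1 was higher by 1.13 (SE 0.13), from 8.74 ± 0.073 to 9.87 ± 0.24. Fabp5, a fatty acid binding protein, was higher by 1.32 (SE 0.29), Neto1 by 1.30 (SE 0.24) and the metalloreductase Steap4 by 1.09 (SE 0.22). With all 6 arrays none of these 12 genes passed, with adjusted p from 0.166 to 0.999 in limma. They were the largest of 118 genes that were higher at an unadjusted p under 0.01 without overlap, 10 of which had no proper symbol.

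Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, had the largest difference towards lower levels in Balb/cBy among the named genes. It stood at 13.2 ± 0.16 in Balb/c and 12.3 ± 0.37 in Balb/cBy (SD, n = 3 each), a log2 difference of -0.91 (SE 0.18). Acaa1b, a peroxisomal thiolase, differed by -0.87 (SE 0.20), and the formin Inf2 by -0.84 (SE 0.13). Mme, which encodes neprilysin, differed by -0.82 (SE 0.22), and Slc17a8, a vesicular glutamate transporter, by -0.80 (SE 0.14). Macroh2a1, a histone variant, differed by -0.75 (SE 0.12), and Fabp2, a fatty acid binding protein of the intestine, by -0.73 (SE 0.20). Smaller differences were those of Depp1 at -0.70 (SE 0.19), the T cell receptor segment Trbv13-2 at -0.66 (SE 0.19), Ntrk2 at -0.66 (SE 0.17), Acads at -0.65 (SE 0.12) and the melatonin receptor Mtnr1a at -0.62 (SE 0.13). None of them passed, with adjusted p from 0.278 for Inf2 and Macroh2a1 to 0.999. They came from 36 genes that were lower at an unadjusted p under 0.01 without overlap, 8 of which had no proper symbol.

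**Figure D1:**
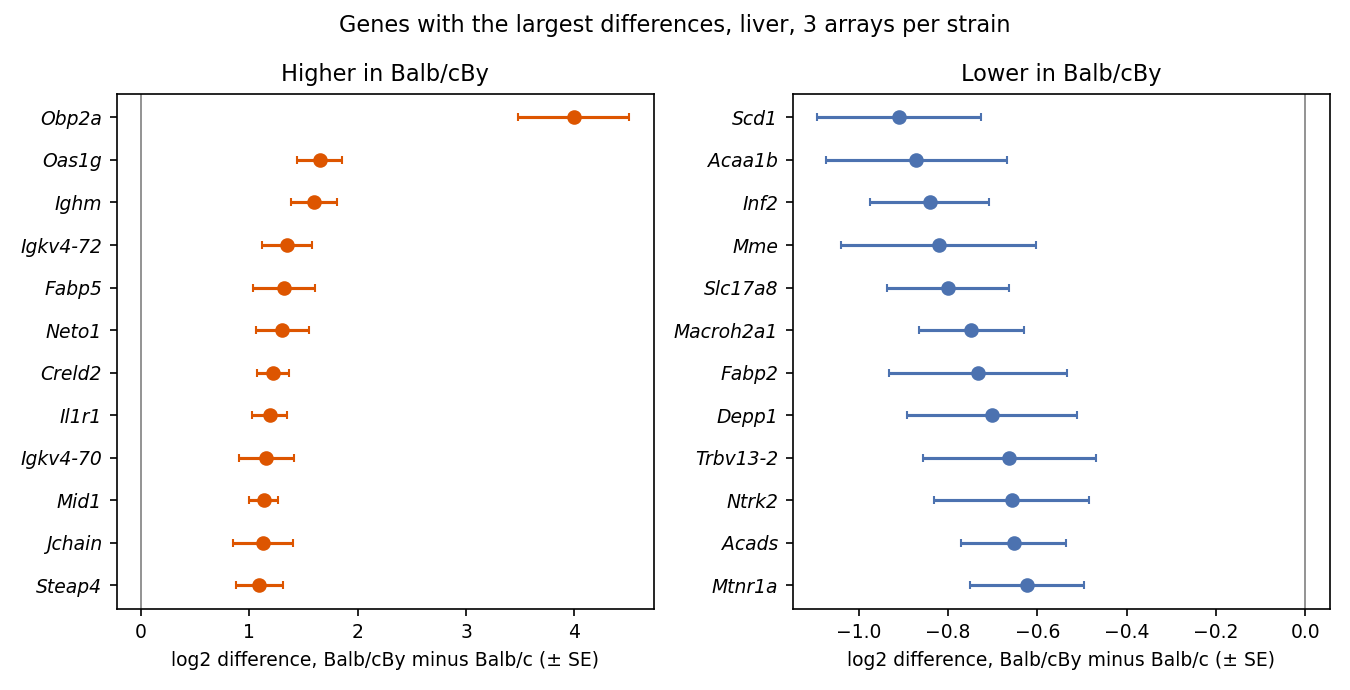
Log2 difference (Balb/cBy minus Balb/c) of the 12 genes with the largest differences in each direction among those with a proper symbol, an unadjusted p under 0.01 and no overlap of the groups, 3 arrays per strain. Points are differences and bars their SE. Obp2a lies at 3.99, apart from the other genes on the higher side, which lie between 1.09 and 1.65; none passed an adjusted p of 0.05.

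Acads stood at 11.4 ± 0.13 in Balb/c and 10.8 ± 0.17 in Balb/cBy (SD, n = 3 each), and the groups did not overlap. The fold of Balb/cBy over Balb/c was 0.636. Its adjusted p was 0.476 over all genes and 0.00927 adjusted over the list alone, and its exact permutation p was 0.1, the smallest that 3 against 3 allows. It was read by 1 probe set. Together with Acads, 15 of 18 measured genes of mitochondrial fatty acid beta-oxidation were lower in Balb/cBy, with a median of -0.08. Over the list alone 1 member passed, and 0 did over all genes. Hadh, the hydroxyacyl-CoA dehydrogenase, had the next smallest p and differed by -0.14 (SE 0.09). The list passed camera (adjusted p = 0.00413), but not with an estimated correlation (adjusted p = 0.727 with an estimated correlation). Without Balb/cBy replicate 1 its median was 0.02 (adjusted p = 0.743), and the call also ended without Balb/c replicate 1 (adjusted p = 0.0762) or Balb/c replicate 3 (adjusted p = 0.0722), while the median was -0.15 without Balb/c replicate 2 and -0.17 without Balb/cBy replicate 2.

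**Figure D2:**
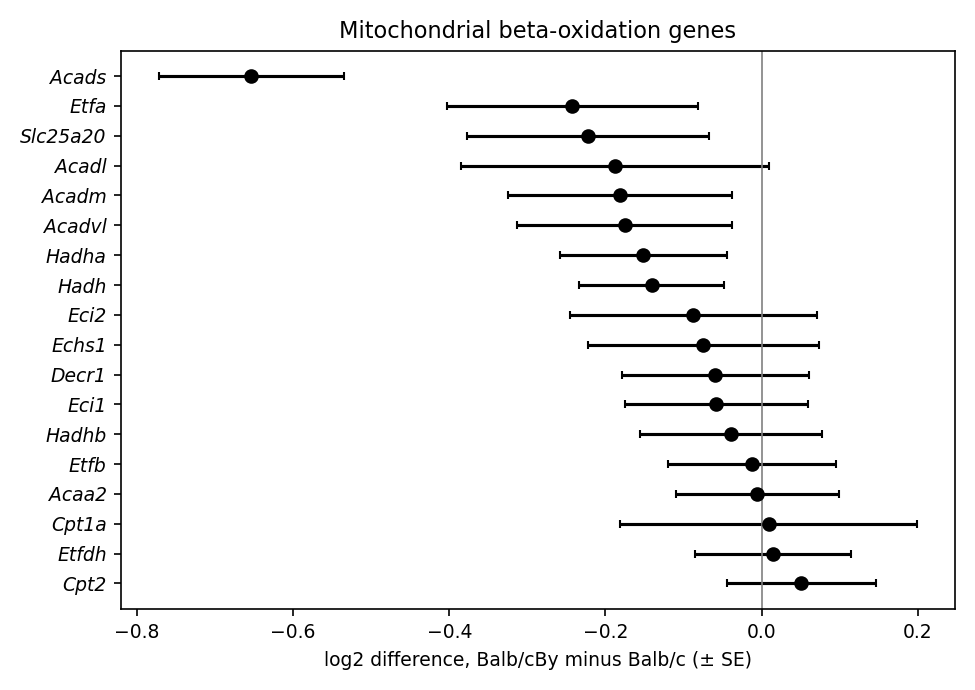
Log2 difference (Balb/cBy minus Balb/c) of the 18 measured genes of mitochondrial fatty acid beta-oxidation, 3 arrays per strain. Points are differences and bars their SE. Acads lies at -0.65, and Etfa, the next, at -0.24.

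Zhx2, a transcriptional repressor of fetal liver genes, differed by 0.13 (SE 0.10, adjusted p = 0.999), from 9.32 ± 0.16 in Balb/c to 9.45 ± 0.026 in Balb/cBy (SD, n = 3 each). Without Balb/c replicate 2 the difference of Zhx2 was 0.04. The labels do not give the supplier of the mice, and so not whether these Balb/c mice carry the Zhx2 variant known from the J substrain. Of 9 measured genes described as under its control, itself included, 4 were higher and 5 lower. The list did not pass (adjusted p = 0.756), its median of -0.03 and mean of -0.01 lay below 0, and camera gave the direction upward. Cyp4a12a, a fatty acid hydroxylase of male liver, differed by 0.34 (SE 0.19), and lipoprotein lipase, Lpl, by 0.30 (SE 0.22). These were 0.16 for Cyp4a12a without Balb/c replicate 2 and 0.09 for Lpl without Balb/cBy replicate 3.

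Genes of the unfolded protein response and amino acid response were higher in Balb/cBy, 16 of 18 measured, with a median of 0.34. Creld2 stood at 10.6 ± 0.068 in Balb/c and 11.8 ± 0.29 in Balb/cBy (SD, n = 3 each), a 2.33-fold difference. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, was 1.81-fold higher (log2 difference 0.85, SE 0.23), and the secreted stress factor Manf 1.56-fold higher (0.65, SE 0.09). Hspa5, the chaperone BiP, was higher by 0.58 (SE 0.12), asparagine synthetase, Asns, by 0.39 (SE 0.12), and the transcription factor Atf4 by 0.34 (SE 0.11). These 6 genes passed when adjusted over the list alone, and 0 passed over all genes. The list passed camera (adjusted p = 3.4e-10) and did not pass with an estimated correlation (adjusted p = 0.104 with an estimated correlation) or with fry (adjusted p = 0.0663). Each of the 3 Balb/cBy arrays had a list mean above that of each Balb/c array, and the exact permutation p was 0.1. The camera call held without each array in turn and in the 8 other settings with the preset correlation. The median was lowest, at 0.22, without Balb/c replicate 2. Camera also called this list in some groupings of 3 arrays against 3 that mixed the strains (adjusted p = 0.0305, 0.0391 and 0.0441). Other mixed groupings did not pass, with camera adjusted p from 0.0511 to 0.907. The call therefore does not by itself set strain apart, although its adjusted p was smallest for strain.

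**Figure D3:**
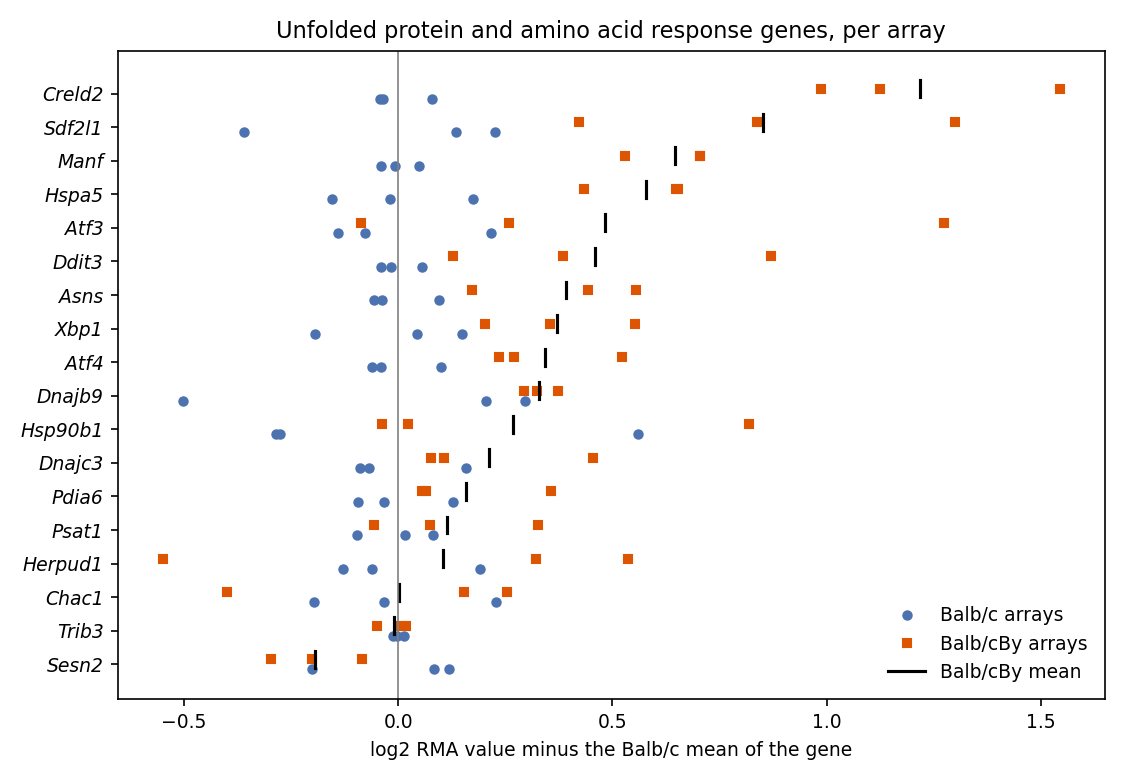
Log2 RMA values of the 18 measured genes of the unfolded protein and amino acid response, each array minus the Balb/c mean of the gene. Circles are Balb/c arrays, squares Balb/cBy arrays, and black bars the Balb/cBy mean. For Creld2 the Balb/cBy mean lies 1.22 above that of Balb/c; Sesn2 and Trib3 lie below 0.

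Heat shock genes were higher as a list, 8 of 11 measured, with a median of 0.32 (camera adjusted p = 0.00413; adjusted p = 0.323 with an estimated correlation). Hspb1, a small heat shock protein, was higher by 0.97 (SE 0.17), and it was the 1 member that passed when adjusted over the list alone (0.00489), while 0 passed over all genes. Bag3, a cochaperone, differed by 0.62 (SE 0.24). The list means were spread within Balb/cBy, at -0.27, 0.55 and 0.26 for replicates 1, 2 and 3, and the median was 0.73, 0.11 and 0.14 without each of them in that order. The NRF2 and metallothionein list did not pass (median 0.03, adjusted p = 0.469), with the metallothionein Mt1 at 0.88 (SE 0.33) and the sulfiredoxin Srxn1 at 0.38 (SE 0.17).

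Interferon response genes were higher in Balb/cBy, 17 of 18 measured, with a median of 0.18. Stat2, a transcription factor of type I interferon signalling, differed by 0.41 (SE 0.10), and Usp18, which removes ISG15 from proteins, by 0.66 (SE 0.19). The list passed camera (adjusted p = 6.24e-07), not with an estimated correlation (adjusted p = 0.323 with an estimated correlation), and 0 members passed over the list alone or over all genes. Genes of MHC class I and antigen processing did not pass as a list (6 of 13 higher, median -0.01, adjusted p = 0.616), with H2-T10 at -0.24 (SE 0.12) and H2-Q4 at -0.19 (SE 0.20). H2-T10 was at -0.14 without Balb/cBy replicate 3, and H2-Q4 at -0.01 without Balb/cBy replicate 1. Acute phase genes of the liver passed camera upward, 16 of 18 higher, with a median of 0.13 (adjusted p = 0.00413; adjusted p = 0.715 with an estimated correlation), and 0 members passed over the list alone or over all genes. Saa4 differed by 0.27 (SE 0.10) and Orm3 by 1.10 (SE 0.52), or 0.58 without Balb/c replicate 3 and 1.66 without Balb/c replicate 2. Balb/c replicate 3 stood apart from the other arrays in this list, with a mean of -0.68 against 0.16 and 0.29 in the other Balb/c arrays. The acute phase call ended without it (median 0.06, adjusted p = 0.933) and without Balb/cBy replicate 1 (median 0.07, adjusted p = 0.165), while the median was 0.20 without Balb/c replicate 2.

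PPAR-alpha target genes of peroxisomal and omega oxidation were lower in Balb/cBy, 16 of 19 measured, with a median of -0.19. Acaa1b stood at 10.9 ± 0.11 in Balb/c and 10.1 ± 0.45 in Balb/cBy (SD, n = 3 each) and passed when adjusted over the list alone (0.0478), the 1 member to do so, while 0 passed over all genes. Acot1, an acyl-CoA thioesterase, differed by -0.42 (SE 0.14). The list passed camera (adjusted p = 3.87e-06), not with an estimated correlation (adjusted p = 0.411 with an estimated correlation). Its call held without each array in turn, although the list mean of Balb/cBy replicate 2, at 0.08, lay above those of Balb/c replicates 2 and 3, at 0.03 and 0.02. Genes of ketone body and branched-chain amino acid catabolism were lower too, 17 of 18 measured, with a median of -0.10 (camera adjusted p = 0.00413; adjusted p = 0.715 with an estimated correlation), and 0 passed over the list alone or over all genes. Hibch, a hydrolase of valine breakdown, differed by -0.43 (SE 0.17), and Dld, the dihydrolipoamide dehydrogenase, by -0.34 (SE 0.16), which were -0.23 and -0.18 without Balb/c replicate 3. That call ended without Balb/c replicate 1 (adjusted p = 0.065), Balb/c replicate 3 (adjusted p = 0.169) or Balb/cBy replicate 1 (median -0.02, adjusted p = 0.556), and its median was -0.20 without Balb/c replicate 2 and -0.18 without Balb/cBy replicate 2.

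**Figure D4:**
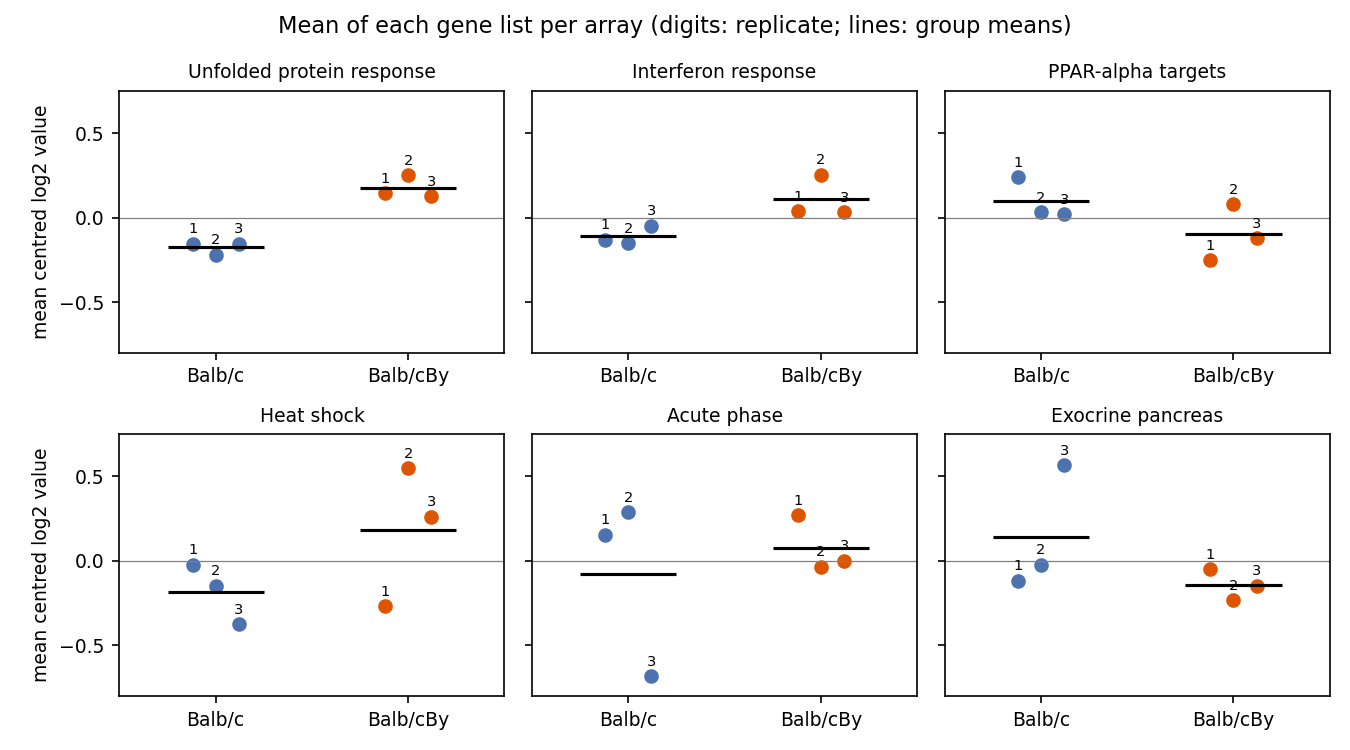
Mean of the centred log2 values of 6 gene lists in each array, where digits give the replicate and lines the group means. The 3 Balb/cBy arrays lie above the 3 Balb/c arrays for the unfolded protein response and the interferon response. Balb/c replicate 3 lies at -0.68 for acute phase genes and at 0.57 for exocrine pancreas markers.

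Markers of other cell types differed in both directions. Stellate cell and collagen genes were higher in Balb/cBy, 13 of 17, with a median of 0.09 (camera adjusted p = 0.00568; adjusted p = 0.727 with an estimated correlation). Lumican, Lum, was higher by 0.53 (SE 0.12) and was the 1 member past 0.05 over the list alone (0.0291), with 0 over all genes, and decorin, Dcn, differed by 0.48 (SE 0.14). Macrophage and Kupffer cell markers were higher, 14 of 19, with a median of 0.11 (camera adjusted p = 0.0124; adjusted p = 0.727 with an estimated correlation), and 0 passed over the list alone or over all genes. Gpnmb differed by 0.36 (SE 0.10) and the perforin-like Mpeg1 by 0.35 (SE 0.12). Without Balb/c replicate 3 the macrophage list turned (median -0.06, adjusted p = 0.794) and the stellate list lost its call (median -0.03, adjusted p = 0.476). Without Balb/cBy replicate 3 both calls ended (adjusted p = 0.133 and 0.19), the stellate median then being 0.03. The macrophage median was 0.26 without Balb/c replicate 2, 0.20 without Balb/cBy replicate 1 and 0.05 without Balb/cBy replicate 2. With a repeated quantile normalization both lists passed, with medians of 0.02 (stellate, adjusted p = 0.0278) and 0.06 (macrophage, adjusted p = 0.0487). Neutrophil markers were higher, 9 of 12, with a median of 0.11 (camera adjusted p = 0.00528; adjusted p = 0.323 with an estimated correlation), and 0 passed over the list alone or over all genes. Retnlg differed by 0.40 (SE 0.11), at low levels of 6.05 in Balb/c and 6.44 in Balb/cBy, and S100a8 by 0.29 (SE 0.12). The neutrophil call ended without Balb/c replicate 3 (median 0.06, adjusted p = 0.122), Balb/cBy replicate 1 (adjusted p = 0.0552) or Balb/cBy replicate 3 (median 0.06, adjusted p = 0.0641), and with either filter on low values (adjusted p = 0.512 and 0.0924). Its median was 0.16 without Balb/c replicate 2.

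Lymphocyte and NK cell markers were lower in Balb/cBy, 13 of 15, with a median of -0.11 (camera adjusted p = 0.00568; adjusted p = 0.417 with an estimated correlation). Ighm was 1 of the 2 members that were higher, and it was the 1 member that passed over the list alone, with 0 over all genes. Ms4a1, the B cell antigen CD20, differed by -0.27 (SE 0.09). Its levels were low, at 6.32 in Balb/c and 6.05 in Balb/cBy, where the lower quartiles of the arrays lay between 6.57 and 6.67. The lymphocyte call ended without Balb/c replicate 2 (adjusted p = 0.0579) or Balb/cBy replicate 1 (adjusted p = 0.0552). Cell cycle genes were lower as well, 14 of 19, with a median of -0.07 (camera adjusted p = 0.0149; adjusted p = 0.411 with an estimated correlation), and 0 passed over the list alone or over all genes. Cdc20 differed by -0.22 (SE 0.11) and Ccnb2 by -0.23 (SE 0.13). The cell cycle call ended without Balb/c replicate 1 (median -0.04, adjusted p = 0.225), Balb/c replicate 2 (adjusted p = 0.0528) or Balb/cBy replicate 1 (median -0.05, adjusted p = 0.203), and its median was -0.02 without Balb/cBy replicate 3.

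Exocrine pancreas markers were lower in Balb/cBy, 10 of 10 measured, with a median of -0.26 (camera adjusted p = 0.000589; adjusted p = 0.681 with an estimated correlation), and 0 passed over the list alone or over all genes. The elastase gene Cela3b differed by -0.35 (SE 0.16) and chymotrypsinogen, Ctrb1, by -0.60 (SE 0.30). This difference came with Balb/c replicate 3, whose list mean was 0.57 while the other 5 arrays lay between -0.23 and -0.02. Without Balb/c replicate 3 the median was -0.09 (adjusted p = 0.239), with Cela3b at -0.19 and Ctrb1 at -0.19.

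The remaining lists of lipid and energy metabolism did not pass, and 0 of their members passed over all genes. Fatty acid and triglyceride synthesis had a median of 0.01, while its mean of -0.05 and camera pointed downward (adjusted p = 0.368). Scd1 was the 1 member past 0.05 over the list alone (0.0212), and Elovl5 differed by -0.41 (SE 0.19), or -0.22 without Balb/c replicate 3. Bile acid synthesis and transport had a median of -0.05 (adjusted p = 0.407), with opposite differences of Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.24 (SE 0.39) and of its repressor Nr0b2 at -0.44 (SE 0.16). Cholesterol synthesis and uptake had a median of 0.07 (adjusted p = 0.159), with Sqle at 0.33 (SE 0.14) and Fdps at 0.58 (SE 0.28). These were 0.17 for Sqle without Balb/cBy replicate 2 and 0.25 for Fdps without Balb/c replicate 3. Lipid droplet and steatosis-associated genes had 9 of 18 members higher (adjusted p = 0.76), with G0s2, an inhibitor of lipolysis, at -0.59 (SE 0.27), or -0.30 without Balb/cBy replicate 2, and Plin3 at 0.20 (SE 0.10). Acyl-CoA synthetases, thioesterases and conjugation had a median of -0.05 (adjusted p = 0.407), with Acss2 at -0.26 (SE 0.18) and Glyat at -0.18 (SE 0.19). Gluconeogenesis, glycogen and insulin signalling had a median of -0.06 (adjusted p = 0.681), with Igf1 at 0.25 (SE 0.15) and the glycogen phosphorylase Pygl at -0.17 (SE 0.11). Oxidative phosphorylation had a median of 0.01, while its mean of -0.01 and camera pointed downward (adjusted p = 0.797), with Ndufs1 at -0.26 (SE 0.14) and Cycs at -0.21 (SE 0.15). Over their lists alone, 0 members of these lists other than Scd1 passed. Leaving out 1 array made calls in 4 of these lists. Without Balb/cBy replicate 2 these were fatty acid synthesis (median -0.17, adjusted p = 0.000609), acyl-CoA synthetases (-0.10, 0.00959) and bile acids (-0.14, 0.029). Without Balb/c replicate 2 they were acyl-CoA synthetases (-0.07, 0.0161) and bile acids (-0.24, 0.00623), and cholesterol synthesis passed without Balb/c replicate 1 (0.22, 0.0173) or Balb/cBy replicate 1 (0.26, 0.000517).

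Lists of sex-biased, drug-metabolising and clock genes and of the other cell types did not pass either, and 0 of their members passed over the list alone or over all genes. Drug-metabolising P450 and conjugating enzymes had a median of 0.05 (adjusted p = 0.128), with Cyp2c54 at 0.48 (SE 0.18) and Sult1a1 at 0.31 (SE 0.12). Male-biased liver genes had a median of 0.08 (adjusted p = 0.341), with Serpina1e at 0.26 (SE 0.10) and Cyp4a12a as given for the Zhx2 list. Female-biased liver genes had a median of -0.04 (adjusted p = 0.696), with Sult3a1 at 0.29 (SE 0.11) and Hao2 at -0.19 (SE 0.11). The levels of Sult3a1 were low, at 4.51 in Balb/c and 4.81 in Balb/cBy. Circadian clock genes had a median of -0.03 (adjusted p = 0.481), with Bhlhe40 at -0.31 (SE 0.12) and Hlf at -0.20 (SE 0.15). Cholangiocyte markers had a median of -0.09 (adjusted p = 0.171), with Cftr at -0.16 (SE 0.11) and Tspan8 at -0.12 (SE 0.09). Liver endothelial markers had 6 of 12 members higher (adjusted p = 0.616), with Fcgr2b at -0.30 (SE 0.15) and Kdr at -0.23 (SE 0.13). Adipocyte markers had a median of -0.02, while their mean of 0.05 and camera pointed upward (adjusted p = 0.979), with Car3 at -0.21 (SE 0.10) and adiponectin, Adipoq, at 0.29 (SE 0.19). The erythroid list rested on 3 measured genes (median 0.02, adjusted p = 0.504), with Slc4a1 at 0.18 (SE 0.10) and Epor at 0.02 (SE 0.09), since the haemoglobin genes had no probe set with 1 symbol. Without Balb/c replicate 3, male-biased genes (median 0.14, adjusted p = 0.000142) and P450 enzymes (0.07, 0.0195) passed, and without Balb/cBy replicate 3 endothelial markers did (-0.11, 0.0151).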

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

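The lists without Acads and without Ighm were tested only after the data were seen. Acads was lower in Balb/cBy in every setting run, with log2 differences from -0.73 to -0.57, and passed in none. The unfolded protein response, interferon, PPAR-alpha and heat shock lists passed camera in all 8 other settings with the preset correlation and without each array, but not with an estimated correlation or fry. Of the values of other named genes over the settings, 1314 kept direction and side of the threshold, 11 passed where they had not, and 3 changed sign. Of 85 named genes, 38 had a log2 difference moved by more than 1.5 times without some array, and of the 24 with the largest differences 0 did. With 3 arrays per group, the number of arrays limits the precision, and no scanner background was used here. The cause was not tested for any change between settings given in these paragraphs.

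Array weights (0.467 for Balb/cBy replicate 1, 0.631 for Balb/c replicate 3, and up to 2.53) gave 12 genes, 11 higher (Bmyc, Creld2, Hyou1, Ighm, Krt8, Manf, Mid1, Oas1g, Obp2a, Syvn1 and Ubtd1) and 1 lower (Macroh2a1). An unadjusted p under 0.05 with a fold of at least 1.5 gave 100 genes, 79 higher and 21 lower. Leaving out single arrays gave 0 to 3 genes, all 0 to 3 of them higher: Obp2a and Oas1g without Balb/c replicate 3, and Ighm, Igkv15-103 and Igkv4-70 without Balb/cBy replicate 1. Lists passing numbered 0 with an estimated correlation, 0 with fry, and 8 to 16 without single arrays. Array weights ended the calls of beta-oxidation (adjusted p = 0.0507), ketone and branched-chain amino acid catabolism (0.06) and acute phase genes (0.0723). A repeated quantile normalization ended that of cell cycle genes (0.0659), and the filter at the median that of lymphocyte markers (0.0906). The medians of beta-oxidation, at -0.13, and of ketone and branched-chain amino acid catabolism, at -0.15, moved with the repeated quantile normalization, those of stellate (0.0196) and macrophage markers (0.0579) did too, that of acute phase genes was 0.0757 with array weights, and that of neutrophil markers 0.0507 with the filter at the median. Without single arrays the median turned for beta-oxidation (0.0164 without Balb/cBy replicate 1) and stellate genes (-0.0255 without Balb/c replicate 3), and 7 lists that did not pass gained a call. Without Acads the beta-oxidation list had a median of -0.07 (adjusted p = 0.0246), and without Ighm the lymphocyte list one of -0.12 (adjusted p = 0.00015).

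The replicate numbers do not pair the arrays: deviations from the group means correlated at -0.323, -0.201 and -0.228 between arrays of the same number, and no array correlated best with its own number. With the replicate block 0 genes passed, with 511 at an unadjusted p under 0.05, and 13 lists passed.

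Camera turned its direction in some settings for lists that did not pass and for the macrophage list. Their medians without single arrays ranged from -0.100 to 0.0098 for acyl-CoA synthetases, -0.171 to 0.153 for fatty acid synthesis, -0.0803 to 0.0840 for lipid droplet genes, -0.0991 to 0.256 for cholesterol synthesis, -0.240 to 0.0838 for bile acids, -0.107 to 0.0717 for gluconeogenesis, -0.0338 to 0.0741 for oxidative phosphorylation, -0.0102 to 0.122 for P450 enzymes, -0.0127 to 0.143 for male-biased and -0.151 to 0.0211 for female-biased genes. They ranged from -0.0506 to 0.0723 for the Zhx2 list, -0.0344 to 0.107 for NRF2 genes, -0.0971 to 0.0643 for MHC class I, -0.0980 to 0.122 for clock genes, -0.110 to 0.0600 for endothelial, -0.0845 to 0.117 for adipocyte and -0.0580 to 0.261 for macrophage markers. Glyat ranged from -0.31 to 0.0540 and Epor from -0.0055 to 0.0647. Where array weights turned the direction, the medians were -0.0643 for lipid droplet genes, 0.0097 for gluconeogenesis, 0.0165 for MHC class I, 0.0863 for clock genes and 0.0394 for endothelial markers. For adipocyte markers camera turned downward after recentring (median -0.0039) and with the filter at the median (-0.0329) or the lower filter (-0.0209), where the median kept its sign, while array weights kept the direction and turned the median to 0.184.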

Other observations

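The covariate tests, the comparison of beta-oxidation members, the pancreas tests, the immunoglobulin list and the branches of the unfolded protein response list were chosen only after the results were seen. The list of other endoplasmic reticulum genes had its bound written before it was run. The immunoglobulin covariate replaced an earlier test of plasma cells on the markers given below. That test had gone against plasma cells, but most of its markers lay near the array medians in level, so it does not decide either. The bounds of the heat shock test and of the pancreas test without Balb/c replicate 3 were reworded after their values were seen, with the same outcomes.

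The immunoglobulin list was drawn up after Ighm, Jchain and 2 kappa segments had been seen among the largest differences. Its values therefore describe and do not test a strain difference of these genes. Of 21 measured heavy and light chain genes with Jchain, 21 had a mean above that of Balb/c, with a median difference of 0.94. Of these, 14 reached an unadjusted p under 0.05, and over all genes 0 passed. Ighg3 differed by 0.02 (SE 0.10). The list means of Balb/cBy replicates 2 and 3, at 0.64 and 0.82, lay far from that of Balb/cBy replicate 1, at -0.16, while the Balb/c arrays lay between -0.51 and -0.34. Markers of plasma cells outside the immunoglobulin genes, such as Mzb1 and Tnfrsf17, had a mean difference of -0.01 (SE 0.04). Near-identical variable segments share probes, so single segments are uncertain.

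Within the unfolded protein response list, chaperones and targets of XBP1 or ATF6 were higher in 10 of 10 members, with a mean of 0.47 (SE 0.08). Members of the ATF4 branch were higher in 6 of 8, with a mean of 0.20 (SE 0.13). The difference between the branches was not tested. Afp, which Zhx2 represses in adult liver, stood at 7.75 ± 0.10 in Balb/c and 7.83 ± 0.058 in Balb/cBy. Among the 17824 probe sets not tested as genes, 0 passed in limma (smallest adjusted p 0.419, 649 at an unadjusted p under 0.05). A probe set assigned to the MHC class I genes H2-Q6 and H2-Q8 stood at 10.3 ± 0.13 in Balb/c and 8.88 ± 0.36 in Balb/cBy (adjusted p = 0.694 among them). Its log2 difference was -1.41 (SE 0.20), farther below 0 than that of Scd1 at -0.91.

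The mean difference of the unfolded protein response list was 0.35 in the real split and at most 0.16 in the others, so 1 of 10 splits gave a value as large, and 10 splits are too few for a share under 0.05. Plasma cells are rich in such transcripts. With the immunoglobulin mean of each array as a covariate, the strain difference was 0.320 (SE 0.0862, 95% interval 0.0461 to 0.594). For a general heat or handling stress, with the heat shock mean as covariate, it was 0.320 (SE 0.0541, interval 0.148 to 0.492). Both lower bounds lay above 0, which argues against RNA of plasma cells or such a stress as the whole cause. A part from either is not excluded, since each fit had 3 residual degrees of freedom and a wide interval. Within Balb/cBy the immunoglobulin mean was -0.16 in replicate 1 against 0.64 and 0.82 in replicates 2 and 3. Of other endoplasmic reticulum genes, 81.25% (39 of 48) were higher (camera p 1.16e-10, 0.0883 with an estimated correlation, exact permutation p 0.2). This met the bound written for an effect on this organelle beyond the fixed list. The array means overlapped, however: Balb/cBy replicate 3, at -8.1e-05, lay below Balb/c replicate 1, at 0.016, and Balb/c replicate 2 was lowest, at -0.20. The count therefore does not by itself set strain apart. A strain effect on the endoplasmic reticulum stays open beside chance and untested differences between the mice.

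Acads was lower in Balb/cBy without overlap. The median of the other beta-oxidation members was -0.0745, above the bound of -0.417 set by Acads and 2 SE. A general decrease of the size seen in the other members would thus fall short of the Acads difference. The bound was set after these values had been seen, so it describes the gap and does not test a cause. A sequence variant under the probes cannot be told apart from a lower transcript level, because Acads has 1 probe set. Whether the known deletion could lower the transcript itself was not tested.

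Exocrine pancreas markers were highest in Balb/c replicate 3 for 9 of 10 genes, as pancreatic tissue carried into that liver sample would give. This count was chosen after the high mean of the same markers in that array was seen. It restates that mean and does not test the hypothesis. Ctrb1 stood at 9.69 in Balb/c replicate 3 and between 8.19 and 8.45 in the other arrays. A strain difference present in every array cannot be told apart from chance, since without Balb/c replicate 3 the list median was -0.0879 (adjusted p = 0.239). The same array had the lowest acute phase mean.

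Across the 10 splits of the 6 arrays, the real one gave 0 genes and the highest other 1. Every split reaches a count of 0, so the gene counts could not tell the splits apart. For lists, the real split gave 13 against a highest other of 16, with 5 splits giving as many. These splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 833 genes, and the split of Balb/c replicate 1 with Balb/cBy replicates 2 and 3 against the rest gave 2989, the highest of the 10. That split follows the leading principal component, which held 34.5% of the variance and placed those 3 arrays, at -2.94, -26 and -12.8, below the others. The count and the component are therefore 1 observation, that the largest spread of the arrays did not follow strain, and its cause was not tested.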
